A study of Homo sapiens with 3 samples.

How the data were processed

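RNA of 1.1B4 cells was hybridised to 3 one-colour Agilent arrays. Per the labels' protocols, cells in 9 dishes were grown for 24 h, 6 dishes then received H2O2 for 4 h, RNA of 3 dishes was combined per array, and Cy3-labelled cRNA was made from 100 ng of that RNA. The groups, 1 control array and 2 H2O2 arrays, came from the sample labels. All 3 arrays shared 1 slide and 1 scan; batches of RNA extraction, labelling and spike-in addition are not given in the sources used here.

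Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 9.5.1.1 and its one-colour gene expression protocol, which subtracts a spatial background surface, removes a multiplicative trend and gives surrogate values to spots not above background. The probe annotation names build hg19, per the file headers, and coordinates are given in that build, 1-based, only where their chromosome matched the gene's in the RefSeq table of GRCh38.p14, used for names alone. A table by the authors lists intensity values of 29285 features, 29229 of them probes for transcripts, that matched the scanner values within 1% for 99.9%, 99.9% and 99.7% of probes on the 3 arrays. The fold values of the authors' deposited table are named as a ratio of a mean scaled H2O2 value to a scaled control value. Their median over probes was 0.962. How these values were scaled is not given in the sources used here. They differed in scale from the refit, with 853.9 for EGR4 against a refitted 120-fold.

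Signals (the scanner's processed signal) of repeated spots of a probe were averaged on the log2 scale, after outlier spots (83 on the control array, 59 and 156 on the H2O2 arrays) and control spots were left out. Each array's 75th percentile was then subtracted; it stood at 2180, 2076 and 1375 signal units. A total of 25 probes had no value on an array. A probe was kept where it was well above background on the control array or on both H2O2 arrays, which left 28291 of 41000 probes. The control array had 67.9% of its probes well above background and the H2O2 arrays 67.8% and 64.1%. For each gene name the probe with the highest mean signal was taken, giving 20718 genes, of which 14135 had a current symbol in the RefSeq table. Names are those of the files where no current symbol was found. For a gene not well above background in a whole group, the fold is a bound, "at least N-fold": the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the dim probe's own.

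Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and called at a Benjamini-Hochberg adjusted p under 0.05. The residual variance of a gene rests on 1 degree of freedom, from the 2 H2O2 arrays, joined to 4.25 prior degrees of freedom with a prior SD of 0.20 log2 units, and the lone control array is assumed to vary alike. Nothing but their separate dishes says how independent the arrays are. Gene lists, 39 in all, were tested with camera at a preset correlation of 0.01, with ranks, an estimated correlation and fry as alternatives, and p-values were adjusted over the lists. None of the list calls held with an estimated correlation. With 1 residual degree of freedom, that alternative and fry had little power to call any list, so their lack of calls decides nothing. In simulated data with 200 changed genes among 20718, limma recovered 0% of 2-fold, 28.4% of 4-fold and 97.0% of 16-fold changes, with 3 false calls among 86. With 3108 changed genes, 55.0%, 97.8% and 99.9% of these sizes were recovered and 5.47% of calls were false. The simulation gave all 3 arrays the same spread and had no background floor, dim probes or signal of single spots. Its share of false calls may therefore be lower than that among the calls here. Figures were drawn with matplotlib.

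Before the data were examined, the test, the alternatives, the lists and the rule for named genes were fixed. The rule took the 12 largest rises and falls among called genes with symbols that were well above background and unsaturated on all 3 arrays, up to 4 members of each list by size with called members first, 25 genes always given where measured (PDX1 and NKX6-1 did not pass the filter), and up to 5 genes per direction by lower-bound fold. Other list members, and TRAF1, were named to complete small counts after their values were seen. Some genes that the rule or these counts took in are not reported here, but stayed in the fit and the lists. The limma p-values are two-sided. Alternatives were quantile normalization, normexp background correction (offset 50), median and spike-in scaling, no filter or a filter on all 3 arrays, every probe or the mean of probes, the authors' probe table, trended robust moderation, other thresholds and each H2O2 array left out. The slide as a block was not run because there was 1 slide.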

Results

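Gene expression was measured in 1.1B4 cells, labelled as a human pancreatic islet-derived hybrid cell line, after 4 h with or without hydrogen peroxide (H2O2), an oxidant. Stocks of this line have been described elsewhere as holding rat cells, which was not tested here, so signals on human probes depend on the label. The series held 3 one-colour microarrays: 1 of untreated cells (0 mM H2O2) and 2 of cells given H2O2, at a dose that the labels state as 100 mM. That is far above doses usual for cultured cells, and whether the unit is right was not checked. Each array carried RNA pooled from 3 culture dishes, so that dishes were not shared between arrays. Probes well above background numbered 27828 on the control array, 27807 on H2O2 array 1 and 26274 on H2O2 array 2, of 41000 probes. After scaling, log2 signals of the H2O2 arrays correlated with each other across genes at r = 0.991, and each correlated with the control at 0.964; genes are not independent replicates. The number of arrays, and above all the single control array, limits the precision of every comparison. The fit's p-values measure the spread between the pair of H2O2 arrays only and assume that the control varied as they did.

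The one comparison of the design asks which transcripts differ in these cells after 4 h of H2O2. Among genes measured on all 3 arrays, the largest rises were those of EGR4, by 120-fold, and FOSB, by 116-fold, immediate early transcription factors that cells switch on within minutes to hours of a stimulus. Lists of ATF4 stress targets, inflammatory cytokine genes and host genes of small nucleolar RNAs were higher relative to other genes in the camera test. That test compares a list with the other genes and not with no change, and no list call held with an estimated correlation. That alternative rests on 1 residual degree of freedom and had little power to call any list. Insulin (INS) mRNA fell 12.4-fold, to signals near the background floor, whereas catalase and the superoxide dismutases had no call. In limma's test with Benjamini-Hochberg adjustment, 1148 genes rose and 425 fell among 20718 genes. Of these, 782 rises and 129 falls were of genes measured on all 3 arrays. The unadjusted p was under 0.05 for 3925 genes. Every called gene also differed at least 2-fold from the control on both H2O2 arrays, a criterion that 1272 genes met upward and 528 downward. The share of rises among the calls, 73.0%, depended on the scaling: it was 64.0% after quantile normalization, 84.6% with normexp background correction, 60.3% with median scaling and 21.3% with spike-in scaling. Spike-in scaling lowered the median change of all genes from 0.04 to -0.66 log2 units, while quantile normalization, median scaling and normexp gave -0.05, -0.10 and 0.12. Gene list medians below are given with their value under spike-in scaling where the sign turned. That scaling moved every gene's mean change by the same -0.70 log2 units. A list's distance from the median of all genes was thus the same under both scalings. The 2 H2O2 arrays moved unequally, because their 75th percentiles stood -1.95 and -2.285 log2 units from the spike-in mean. Every gene's spread between these arrays therefore changed, and calls lost with spike-in scaling can reflect this. How far they do was not tested.

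**Figure D1:**
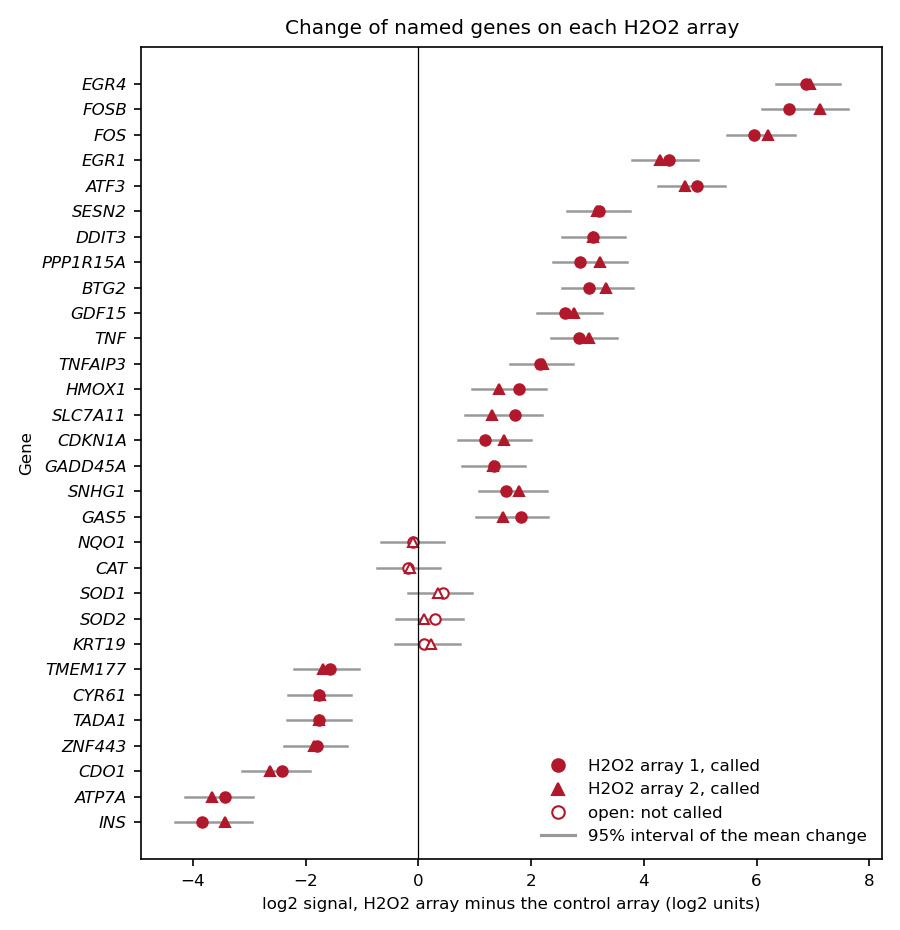
Log2 signal of each H2O2 array minus the control array (x axis, log2 units) for 30 genes (y axis), with circles for H2O2 array 1, triangles for H2O2 array 2, filled symbols for genes with an adjusted p under 0.05 and grey bars for the fit's 95% interval of the mean change. EGR4, at 6.91, lies farthest to the right and INS, at -3.64, farthest to the left, and the interval of CAT spans 0.

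Immediate early genes held the 3 largest rises among genes measured on all 3 arrays. EGR4, FOSB and FOS encode DNA-binding transcription factors. EGR4 (probe at chromosome 2, 73518161 to 73518219, hg19) rose by 6.91 log2 units (SE 0.22, adjusted p = 0.00129), from a scaled log2 signal of -4.21 in the control to 2.70 ± 0.05 (SD, n = 2). FOSB (chromosome 19, 45978205 to 45978264) rose by 6.86 (SE 0.30) and FOS (chromosome 14, 75748214 to 75748273) by 6.07 (SE 0.24). EGR1 rose by 4.37, and ATF3 (chromosome 1, 212793856 to 212793915), a repressor induced by many stresses, by 4.84; a second ATF3 probe gave 5.05. Of 42 measured immediate early genes 23 rose, 1 fell and 18 had no call; adjusted over the list alone, 28 rose and 6 fell. EGR2 and NR4A3 were not well above background in the control and were at least 61.5-fold and 35.6-fold higher after H2O2. A second NR4A3 probe was dim on every array and gave 0.68. MYC was at 0.73 (adjusted p = 0.267). The member that fell was CYR61 (current symbol CCN1), a secreted matrix protein and YAP target, at -1.76 (SE 0.22, adjusted p = 0.0111); its other probes gave -1.84 and -1.96. The list's median was 1.31, and 0.62 with spike-in scaling (camera adjusted p = 5.54e-12; adjusted p = 0.739 with an estimated correlation).

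Genes of the integrated stress response, which ATF4 drives when translation is held back, were also examined. Of 32 measured targets 12 rose and none fell (13 and 0 adjusted over the list alone). SESN2, a brake on growth signalling, rose by 3.19 (SE 0.22, adjusted p = 0.00183). DDIT3, the transcription factor CHOP, rose by 3.10 (SE 0.22, adjusted p = 0.00193), and PPP1R15A, which restores translation, by 3.04 (SE 0.26, adjusted p = 0.00331). The list's median was 0.57, but -0.13 with spike-in scaling (camera adjusted p = 3.75e-06; adjusted p = 0.739 with an estimated correlation). Of 32 p53 targets 7 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.20 that turned to -0.50 with spike-in scaling (camera adjusted p = 0.0341; adjusted p = 0.739 with an estimated correlation). The p53 call was lost with no filter (0.329) and with the authors' probe table (0.0581). BTG2 rose by 3.18, the cytokine GDF15 by 2.68, the cell cycle inhibitor CDKN1A by 1.35 (adjusted p = 0.0404) and GADD45A by 1.33 (adjusted p = 0.0273). SESN2 and GDF15 belong to the ATF4 list and BTG2 to the immediate early list as well. CDKN1A lost its call with spike-in scaling (adjusted p = 0.255). The BCL2 and caspase list was not called (camera adjusted p = 0.087), though it was with quantile normalization (0.029) and the authors' probe table (0.0434), and 3 of its 31 members rose, again 3 adjusted over the list alone: PMAIP1 by 2.27, BCL2L11 by 2.10 and BIK by 1.73, which all encode BH3-only proteins that promote cell death. All 4 probes of BCL2L11 lay between 1.79 and 2.10.

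Antioxidant genes were covered by several lists. HMOX1, the haem-degrading enzyme haem oxygenase 1, rose by 1.61 (SE 0.26, adjusted p = 0.0258), a call lost with spike-in scaling (0.91, adjusted p = 0.133). Among 33 measured targets of the oxidant-responsive factor NRF2, 5 rose and none fell, also 5 adjusted over the list alone. OSGIN1 rose by 2.59, ABCC2, an efflux pump for glutathione conjugates, by 2.03, and SLC7A11, the cystine importer, by 1.51. TXNRD1 (0.59, adjusted p = 0.241), SRXN1 (0.82, adjusted p = 0.128), GCLM (0.43, adjusted p = 0.597) and NQO1 (-0.10, adjusted p = 0.87) had no call. The list's median was 0.30, but -0.40 with spike-in scaling (camera adjusted p = 0.0132; adjusted p = 0.739 with an estimated correlation). Its call was also lost with normexp (0.0593), spike-in scaling (0.137) and no filter (0.227). Of 31 genes for peroxide and superoxide removal none was called by limma, over all genes or adjusted over the list alone, and 4 rose at an unadjusted p under 0.05 (list camera adjusted p = 0.12). The closest to a call was the glutaredoxin GLRX (1.12, adjusted p = 0.0511). Catalase (CAT) was at -0.17 with a 95% interval from -0.73 to 0.39, SOD1 at 0.38, SOD2 at 0.20, GPX1 at 0.79, PRDX1 at 0.34, TXN at 0.30 and TXNIP at 0.64. Of 25 glutathione genes only SLC7A11 rose, and none did adjusted over the list alone (camera adjusted p = 0.137). None of 13 metallothionein and metal response genes was called (camera adjusted p = 0.899), with 0 adjusted over the list alone and 0 at limma's unadjusted p under 0.05, and MT2A was at 0.23.

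Heat shock genes had 3 rises among 26 (6 adjusted over the list alone), with a median of 0.26 that turned to -0.44 with spike-in scaling (camera adjusted p = 0.0264; adjusted p = 0.739 with an estimated correlation). The call was lost with normexp (0.157), spike-in scaling (0.288) and no filter (0.329) as well. The chaperones HSPA6, HSPB8 and CRYAB rose by 1.35, 1.26 and 1.16. The probes of HSPA1A disagreed, at 0.91 (adjusted p = 0.0858), 1.24 and 2.61, and its near-identical copy HSPA1B may share them. Of 26 endoplasmic reticulum chaperone and degradation genes 2 rose, again 2 adjusted over the list alone (camera adjusted p = 0.223). These were HERPUD1, at 1.47, and DERL1, whose 3 probes disagreed at 1.69, 0.29 and -0.01. None of 32 autophagy and lysosome genes was called by limma over all genes or adjusted over the list alone, and 1 rose at an unadjusted p under 0.05 (camera adjusted p = 0.869). Of 35 proteasome genes PSMB4 alone rose, by 1.31 (camera adjusted p = 0.213; none adjusted over the list alone).

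The list of cytokine and NF-kB target genes was called higher than other genes. Of 27 measured members 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.28 that turned to -0.41 with spike-in scaling (camera adjusted p = 0.00429; adjusted p = 0.739 with an estimated correlation), and the call was lost with no filter (0.0635). The chemokine CCL20 was not well above background in the control and was at least 20.9-fold higher after H2O2. TNF rose by 2.94 (SE 0.23, adjusted p = 0.00258), and its second probe gave 2.07. TNFAIP3, a feedback inhibitor of NF-kB, rose by 2.19 and the chemokine CCL5 by 2.10. TRAF1 fell, at -1.44. Of 32 interferon-stimulated genes IFIH1 and ISG20 rose, by 1.27 and 1.13, and none was called adjusted over the list alone (camera adjusted p = 0.836). Hypoxia response genes had 5 rises among 24 (6 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.137), among them DDIT4 at 2.34 and VEGFA at 1.61, whose 4 probes ranged from 0.85 to 1.98.

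Host genes of small nucleolar RNAs, transcripts that carry these guides in their introns, were called higher than other genes. Of 14 measured members 6 rose, and 11 rose and 1 fell adjusted over the list alone. SNHG10 rose by 1.85, SNHG1 by 1.67 (SE 0.24, adjusted p = 0.0167) and GAS5 by 1.66 (SE 0.25, adjusted p = 0.0202). The annotation places the GAS5 probe on chromosome 6, and which transcript it measures was not tested. Their median was 0.92, and 0.23 with spike-in scaling (camera adjusted p = 7.87e-06; adjusted p = 0.739 with an estimated correlation). Of 85 cytosolic ribosomal protein genes 84 had values above 0, with a median of 0.29 (camera adjusted p = 0.000546; adjusted p = 0.757 with an estimated correlation). That median was -0.40 with spike-in scaling, and after quantile normalization it was 0.02, with no call (camera adjusted p = 0.265). The call was also lost with normexp (0.131), spike-in scaling (0.239) and no filter (0.113). Only RPL14 was called, by 1 probe at 1.55 against 0.12 and 0.07 for its others, and no member was called adjusted over the list alone.

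The lists for ribosome biogenesis, mitosis and ZNF zinc finger genes were called lower relative to other genes. Of 438 ZNF genes, mostly KRAB-type repressors, 27 fell and 6 rose (28 and 6 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 8.9e-06; adjusted p = 0.739 with an estimated correlation). ZNF606 fell (-2.13), as did ZNF443 (-1.83), while ZNF436 rose by 5.29 and ZNF862 by 2.63, although a second ZNF862 probe gave 0.37. Of 42 ribosome biogenesis genes PPAN fell (-1.19, adjusted p = 0.0389), none was called adjusted over the list alone, and the median was -0.20 (camera adjusted p = 0.00748; adjusted p = 0.739 with an estimated correlation). Of 48 mitosis genes none was called by limma, over all genes or adjusted over the list alone, while 8 were lower and 1 higher at an unadjusted p under 0.05. Their median was -0.26 (camera adjusted p = 0.00889; adjusted p = 0.739 with an estimated correlation), with MKI67, the Ki-67 proliferation antigen, at -0.71 (adjusted p = 0.179). All 3 list medians stayed below 0 under every scaling, but the mitosis and ribosome biogenesis lists lost their calls with spike-in scaling (camera adjusted p = 0.137 for each).

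**Figure D2:**
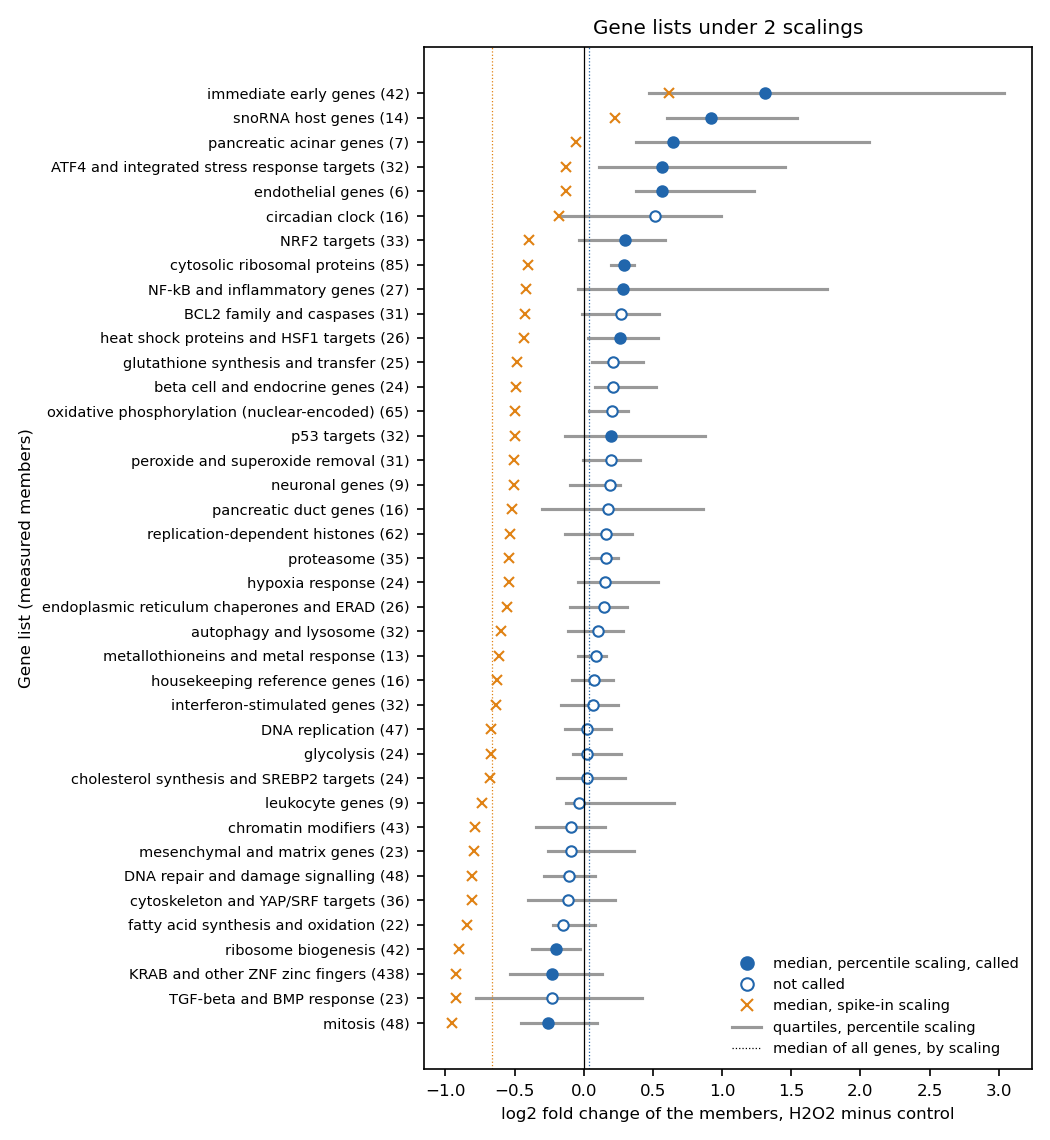
Median log2 fold change of the measured members (x axis) of each of 39 gene lists (y axis, with the number of members), as circles with quartile bars under 75th percentile scaling, filled where camera's adjusted p was under 0.05, and as crosses under spike-in scaling. The immediate early list lies highest at 1.31 and the mitosis list lowest at -0.26, and with spike-in scaling only the immediate early (0.62) and small nucleolar RNA host (0.23) medians lie above 0.

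Under 75th percentile scaling, 129 of the called falls were measured on all 3 arrays. INS (chromosome 11, 2181064 to 2181123) fell from a scaled log2 signal of -1.41 to -5.05 ± 0.29 (SD, n = 2), a change of -3.64 (SE 0.27, adjusted p = 0.00211). It was measured by 1 probe, so that its control level rests on that probe on 1 array. After H2O2 it stood at -5.25 and -4.84. The lowest signals well above background on these arrays were -6.17 and -5.40, so the size of its fall rests on signals near the floor. The copper transporter ATP7A (-3.54, adjusted p = 0.00169) and the cysteine dioxygenase CDO1 (-2.53, adjusted p = 0.00439) also fell. CDO1 stood at -5.06 and -5.29 after H2O2, also near the floor. AMY1C fell (-3.88), but near-identical amylase genes may share its probe. FOXA1, a transcription factor of endodermal tissues, fell by its brighter probe (-2.27), and its other probe, dim on H2O2 array 2, was too near the floor to compare. TADA1, a subunit of a histone acetylation complex, and TMEM177, a mitochondrial membrane protein, fell as well (-1.76 and -1.63). Of the rises, MCRS1 (5.18), PYGM (4.85), ACTA1 (4.77), TAC3 (4.64), CCL17 (4.57) and ARL14 (4.53) were smaller than FOS and larger than EGR1. TIFA rose by 5.13, whereas its dimmer probe gave -1.095. That probe was well above background in the control but not on either H2O2 array.

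Many calls were of genes not well above background in one group. A gene dim in the control passed the filter only if it was bright on both H2O2 arrays. The filter thus all but set its direction: of 408 such genes, 366 were called higher and 0 lower. Genes dim on both H2O2 arrays passed only if bright in the control, and of 895 such genes 264 were called lower and 0 higher. Of the rises, 782 were measured on all 3 arrays and 366 were dim in the control, such as AOC3 (at least 89.0-fold higher), DYRK4 (at least 61.6-fold) and OSM (at least 35.6-fold). Of the falls, 129 were measured on all 3 arrays, 32 were dim on 1 H2O2 array and 264, or 62.1%, were dim on both, such as HBE1 (at least 27.8-fold lower), MAGEC3 (at least 26.6-fold) and KCTD4 (at least 16.7-fold). The other probes of HBE1 and KCTD4 were dim on every array and gave 0.31 and 0.61. To set these against the arrays' own spread, each array in turn was treated as the odd one out. Probes bright on 1 array, dim on both others and at least 2-fold apart numbered 371 for the control, 305 for H2O2 array 1 and 198 for H2O2 array 2. Probes dim on 1 array and at least 2-fold brighter on both others numbered 459 for the control, but 27 and 67 for the H2O2 arrays. The first set of counts differed by less than 2-fold between the control and either H2O2 array, and the second by more. They hold for 75th percentile scaling, since spike-in scaling turned the calls to 627 rises and 2320 falls.

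**Figure D3:**
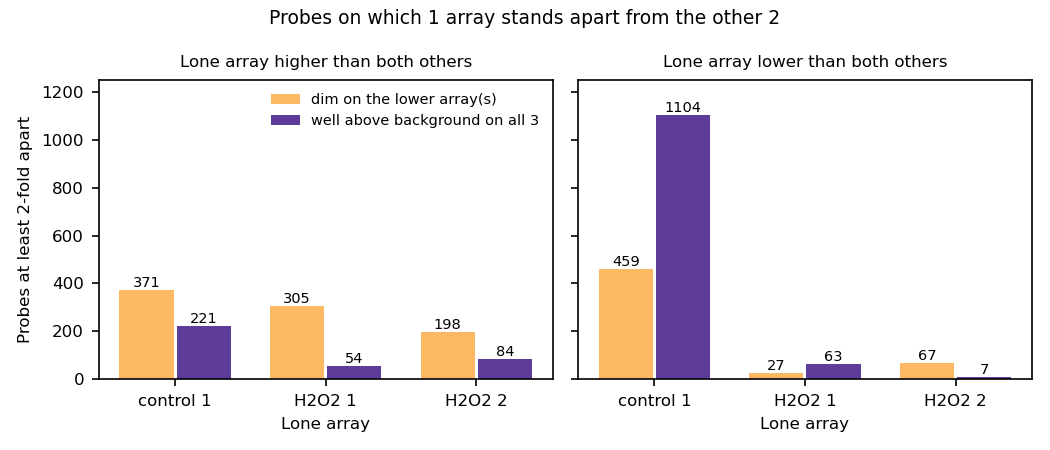
Number of probes (y axis) at least 2-fold higher (left) or lower (right) on 1 array (x axis) than on both others, with orange bars for probes dim on the lower array or arrays and purple bars for probes well above background on all 3. Under 75th percentile scaling, the only one drawn, the control stood apart mostly by being lower, on 1104 probes measured everywhere, whereas its 371 probes bright on that array alone compare with 305 for H2O2 array 1.

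Genes of pancreatic and other cell types were examined next. The beta cell and endocrine list was not called (camera adjusted p = 0.115): of 24 measured members 2 rose and 1, INS, fell, with the same counts adjusted over the list alone. SCG5, a secretory granule chaperone, rose at least 5.98-fold from background. PDX1, a beta cell transcription factor, was well above background on H2O2 array 1 only, and NKX6-1, SLC2A2, PCSK1 and NEUROD1 on no array. KRT19, a duct keratin, was at 0.16 (adjusted p = 0.787), and KRT7 (adjusted p = 0.354) was well above background in the control only, too close to the floor to give a size. Of 16 duct genes ELF3 and CLDN4 rose (5 adjusted over the list alone; camera adjusted p = 0.186). The acinar list, with 7 measured members, had a median of 0.64 that turned to -0.05 with spike-in scaling (camera adjusted p = 0.00429; adjusted p = 0.739 with an estimated correlation), and was not called with no filter (0.073). The 2 members that rose, also 2 adjusted over the list alone, were CTRB1, dim in the control, and CELA2A, whereas PRSS1 and CPA1 were well above background on no array. The endothelial list, with 6 members, had a median of 0.57 that turned to -0.13 with spike-in scaling (camera adjusted p = 0.031; adjusted p = 0.739 with an estimated correlation). Its call was lost with normexp (0.0849) and no filter (0.329), and too few members were above background on all 3 arrays to test. PECAM1 and VWF rose, 2 members again when adjusted over the list alone, both from below background (a second VWF probe, dim on every array, gave 0.80), and CDH5 was dim on every array. Leukocyte genes (2 rises of 9, ITGAM among them; camera adjusted p = 0.155), neuronal genes (1 rise, NEFH, and 1 fall, STMN2, of 9; camera adjusted p = 1) and mesenchymal genes (1 rise of 23, SNAI1 at 2.55; camera adjusted p = 1) were not called, and had the same counts adjusted over the list alone. The leukocyte marker PTPRC and the fibroblast markers COL1A2, DCN and PDGFRA were dim on every array.

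The remaining lists were not called by camera, though some were under other settings: the clock list higher with quantile normalization (0.029), normexp (0.035), median scaling (0.0377) and the filter on all 3 arrays (0.0404). The cytoskeleton list was called lower with normexp (0.0292) and no filter (0.00971), and DNA repair lower with no filter (0.00706). Of 16 circadian clock genes 4 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.072): PER1 by 2.12, RORA by 1.82, NR1D2 by 1.35 and NR1D1 by 1.18, with a second NR1D2 probe at 0.18. Of 23 TGF-beta and BMP response genes BAMBI, ID2 and BMP2 rose, by 2.30, 2.06 and 1.55 (5 rises and 7 falls adjusted over the list alone; camera adjusted p = 0.498). Chromatin modifiers had 3 rises of 43 (1 adjusted over the list alone; camera adjusted p = 0.412): the histone demethylase KDM6B by 1.98, HDAC9 by 1.44 and BRD2 by 1.12. The other 4 probes of HDAC9, each dim on at least 1 array, gave -0.23 to 2.29. Cytoskeleton and YAP or SRF targets had 1 fall of 36, CYR61, also adjusted over the list alone (camera adjusted p = 0.155). DNA replication genes had 1 rise of 47, CLSPN at 1.57, also adjusted over the list alone (camera adjusted p = 0.684), and replication-dependent histones 1 rise and 1 fall of 62, with 1 rise adjusted over the list alone (camera adjusted p = 0.48). Neither over all genes nor adjusted over the list alone did limma call a member among the last 6 lists. At an unadjusted p under 0.05, it had 1 gene higher and 2 lower of 48 DNA repair genes (camera adjusted p = 0.155), 2 higher of 65 nuclear-encoded oxidative phosphorylation genes (0.083) and 2 higher of 24 glycolysis genes (0.734). The same count was 1 higher of 24 cholesterol synthesis genes (camera adjusted p = 1), 1 lower of 22 fatty acid genes (0.213) and 0 of 16 housekeeping genes (0.989). The fry test, which asks whether a list's genes move on balance one way, called none of the 39 lists. With 1 residual degree of freedom it had little power to call any.

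The authors' deposited table gives a fold of the mean H2O2 value over the control for 29229 probes. By that fold, 3125 probes were at least 2-fold higher and 2452 at least 2-fold lower. These fall on 2877 and 2270 gene names, against 2903 and 2283 genes that the submitters stated, with a criterion not given in the sources used here. The authors' fold and the refitted change had a Spearman correlation of 0.962 across probes. Of the probes at least 2-fold apart in the authors' deposited table, 99.9% had the same sign in the refit. Both values compare 2 treatments of the same scanner signals, so they are not independent evidence. A rank correlation does not show a difference in scale, while the share with the same sign can change with the scaling. The authors' folds were larger for top rises: 853.9 against 120 for EGR4 and 380.2 against 67.3 for FOS. A 2-fold cut-off in their table was thus not the one used here.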

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

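All tests in this part were chosen after the result was seen. The 8 spike-in probes above background, added RNA that no comparison between genes uses, were brighter on the H2O2 arrays than on the control, by a mean of 0.33 log2 units (0.46 and 0.20 on the 2 arrays). Every one of the 8 probes was higher, by 0.17 to 0.45. A scan or hybridisation that made the H2O2 arrays brighter overall is argued against, because the 75th percentile of the sample probes was lower on both, by a mean of -0.37 log2 units (-0.07 and -0.66). Still open is whether treated cells held less messenger RNA per total RNA, a possible biological explanation, or whether more spike-in was added per total RNA: these cannot be told apart from the spike-in shift of 0.33, because neither amount was measured in these files. The shift of 0.33 is only part of the -0.70 log2 units between the 2 scalings, which gave 73.0% and 21.3% rises among called genes. Median scaling, quantile normalization and normexp gave 60.3%, 64.0% and 84.6%. Which share holds was not decided here.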

How the results depend on the processing

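Alternatives restricted to genes measured on all 3 arrays among the calls, and list members set to their bound, were chosen after seeing the data; all others were planned. Calls numbered 1148 higher and 425 lower. Falls numbered 224 with normexp, 795 with median scaling, 211 with probes well above background on all 3 arrays and 129 counting only calls measured on all 3. Spike-in scaling gave 627 rises and 2320 falls, no filter 156 and 31, the probe table of the authors 662 and 121, and an adjusted p under 0.01, which is stricter by construction, 563 and 135. Of the 1573 main calls 1327 were shared with quantile normalization, 1570 with median scaling, 1160 with normexp and 1031 with spike-in scaling. Genes at least 2-fold from the control on both H2O2 arrays numbered 1272 and 528; normexp gave 830 and 111, spike-in scaling 631 and 2412, no filter 2466 rises, all 3 arrays above background 161 falls, 1.5-fold 2145 and 1241, and 4-fold 524 and 167. Leaving out an H2O2 array gave 1511 to 1627 rises and 775 to 823 falls (the larger without array 2), with no test. Camera called 10 lists higher and 3 lower; spike-in scaling left 1 lower, no filter 3 higher and 5 lower, ranks 11 and 3, and an estimated correlation and fry 0 and 0. Apart from the settings' own construction, the cause was not tested.

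No named gene with a call reversed its direction. Uncalled genes that turned with spike-in scaling were GCLM (-0.27), TXNRD1 (-0.11), SOD1 (-0.31), SOD2 (-0.50), PRDX1 (-0.36), TXN (-0.40), TXNIP (-0.057), KRT19 (-0.54), MT2A (-0.47), MTF1 (-0.50), PSMC6 (-0.18), PSMA2 (-0.22), ULK1 (-0.17), MAP1LC3B (-0.18), ATP5E (-0.22), COX6C (-0.24), ALDOC (-0.16), PFKFB4 (-0.28), HMGCS1 (-0.015), IDI1 (-0.13), SREBF1 (-0.13), PRSS3 (-0.053), CD14 (-0.042), CD8A (-0.075), ERG (-0.12), ESAM (-0.14), SYP (-0.13) and ACTB (-0.37). Quantile normalization turned KRT19 (-0.11), MT2A (-0.11) and ACTB (-0.012), normexp KRT7 (0.058), the mean of probes MTF1 (-0.11) and YWHAZ (0.22), and leaving out an H2O2 array PRSS3 (-0.022 without array 2, 1.31 without array 1) and POLR2A (-0.99 and 0.044). With spike-in scaling the medians of called lists turned for NRF2 targets (-0.40), heat shock (-0.44), ATF4 (-0.13), p53 (-0.50), NF-kB (-0.41), ribosomal protein (-0.40), acinar (-0.053) and endothelial genes (-0.13), as every gene's mean change moved down by the same amount. With members at their bound, the medians of called lists were the same to 2 decimals except for ZNF genes (-0.21). No paired analysis was possible because there is a single control array; the authors' column name for it carries a 2 that the sources used here do not explain. With 1 control array no outlier test and no other split of the samples applies. The fraction of probes over background, 64.1% to 67.9%, limits what falls can be measured.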

Other observations

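The tests on other probes of the same gene were chosen after the result was seen, and their cut-off was altered after that; the tests on counts per array and on decay factors were written before their results were seen.

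Some markers fixed for islet and duct cells were measured on all 3 arrays and had no call. The beta cell factor MAFA was at 0.02 log2 units (adjusted p = 0.986), IAPP, the islet amyloid peptide, at 0.60 (adjusted p = 0.315) and HHEX, a delta cell factor, at 0.01 (adjusted p = 0.989). Among duct and epithelial markers SOX9 was at 0.47 (adjusted p = 0.353), MUC1 at 0.19 (adjusted p = 0.742) and EPCAM at 0.12 (adjusted p = 0.863). The fall of INS mRNA thus stood beside other islet markers without a call; whether INS differed from them was not tested. The alpha cell markers GCG and IRX2 and the delta cell hormone SST were not well above background on any array, and CELA3A and AMY2A were not found under those names among the probes.

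For genes that seemed to switch off, probes bright (at least 2 log2 units over the highest floor) on the control alone numbered 44, against 61 on H2O2 array 1 alone and 37 on H2O2 array 2 alone, a ratio of 0.898 to their mean. Other probes of genes called lower and dim after H2O2 followed the fall in 0% of 31 genes (95% exact interval to 11.2%), against 43.5% of 23 called falls measured on all 3 arrays. Signal of single spots or probes as the source of many of these 264 falls would give both values, although a dim second probe may also miss a weak transcript. The brightest probe of each gene was kept, so its others were mostly dimmer, and those of HBE1 and KCTD4 were dim on every array. A dim probe cannot show a fall, so the 0% does not by itself separate these explanations. For switching on, 53 probes were bright on both H2O2 arrays and dim on the control, against 0 and 2 for the other pairs, a ratio of 53 to their mean, which argues against chance signal of single spots. Signal that other probes do not share stays open there, since other probes followed in 18.0% of 61 genes (interval 9.36% to 30%), between the 3.98% of uncalled genes and the 48.3% of rises measured everywhere.

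Under 75th percentile scaling, probes well above background on all 3 arrays gave a different picture. On 76 of them the control lay at least 8-fold below both H2O2 arrays while these were within 2-fold of each other, and on 6 it lay 8-fold above, against 1 and 2 probes above and 1 and 0 below for the H2O2 arrays. INS is among the few that lie above.

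A hypothesis was tested for the small nucleolar RNA host genes, several of which are known to be degraded by nonsense-mediated decay: less of this decay could raise them together. Transcripts of 7 decay factors that are themselves its targets would then rise. Their median was -0.09 log2 units, with UPF3B highest at 0.21 and none called, so the predicted median over 0.5 was not reached. The transcript levels of these factors are not a measure of decay itself, and they rest on a single control array. The test therefore does not decide whether less decay raised the host genes. Under 75th percentile scaling the ribosomal protein genes, with a median of 0.29, and the ATF4 targets moved in the same direction as the host genes. With spike-in scaling they did not, at -0.40 and -0.13 against 0.23 for the host genes. No biological explanation of the shared direction was tested.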
